A study of Nasturtium officinale with 24 samples.

How the data were processed

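The samples came from watercress (Nasturtium officinale), a semi-aquatic plant of the cabbage family. Per the labels' protocols, plants were about 3 weeks old, grew with 8 h of light and 16 h of dark at 23 °C and 100 µmol photons per m2 and s, and were then either put completely under water or kept in air. Stems and petioles (the leaf stalks) were collected separately after 1 day and after 2 days, with 5 plants pooled in each sample. The design therefore crosses 2 tissues, 2 treatments and 2 times in 8 groups, with 3 libraries per group and 24 libraries in all. The labels speak of 3 replicates, each a pool of its own plants, so the spread between libraries holds variation between pools of plants as well as technical variation. Whether the stem and the petiole sample of the same number came from the same 5 plants is not stated.

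Per the labels' protocols, messenger RNA was isolated from tissue lysates with magnetic beads, fragmented by heat and turned into libraries with the BrAD-seq protocol in its version that does not keep the strand. The fragments measured 200 to 500 bp and were sequenced from both ends with reads of 100 bp. Because strand was not kept, reads of a transcript and of an overlapping antisense transcript cannot be told apart. Per the submitters' processing notes the tools were kallisto, edgeR and limma, without versions or order. kallisto assigns reads to transcripts by pseudoalignment and splits reads that fit several transcripts between them, so contigs with near-identical copies share reads and their separate values are uncertain. The version of each tool, the transcriptome file and the read filters are not given in the sources used here.

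Each library came as a table of 80741 targets with the length, the effective length, the estimated count and the TPM of each target. The estimated counts are as deposited, are not normalised and need not be whole numbers. The TPM values (transcript abundances that adjust for effective length and sum to a fixed total) are also as deposited, and were not used in any test. The length and the effective length in bases stand beside them per the file headers. The targets are transcript contigs of 201 to 12603 bases (median 697) named by accession-like identifiers, printed here without their database prefix. The files do not pair these identifiers with gene names, and no reference was used here. For this reason 26 gene lists and 6 lists of cell type markers, fixed before the data were examined, were not tested, no gene is named, and the target as deposited was the unit of every count. Several contigs can belong to 1 gene, so numbers of contigs are not numbers of genes.

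Estimated counts were rounded to whole numbers. Library totals lay between 17617430 and 48928331 estimated counts. Of the 80741 contigs, 63905 had a count in at least 1 library and 53919 passed the low-count filter of edgeR (filterByExpr by group, with a minimum count of 10 in a library of median size and a minimum total of 15). The tested contigs held at least 99.92% of the counts of every library. Of the tested contigs, 24.2% had estimated counts that were whole, within 1e-06, in every library. Libraries were scaled with TMM factors. edgeR 4.0.16 fitted 1 mean for each of the 8 groups to all 24 libraries together (estimateDisp, glmQLFit, glmQLFTest), so that the groups shared an estimate of the spread. The biological coefficient of variation was 0.374. The 12 contrasts were written down before the data were examined: submergence against air in each tissue on each day, the tissue by treatment interaction on each day, the time by treatment interaction in each tissue, stem against petiole in air on each day, and 2 days against 1 day in air in each tissue. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 53919 contigs of a contrast, and a contig counted as called at an adjusted p under 0.05. Fold changes are fitted log2 values, their standard errors (SE) were derived from the F statistic, and a positive interaction means a more positive change in stem, or at 2 days. Group means and SD are given as CPM, in which counts are scaled to a common library total, computed here from the deposited estimated counts with TMM-scaled totals.

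The rule for named contigs was also fixed before the data were examined. Because the identifiers name no gene, at most 2 contigs that rose most and 2 that fell most were named per contrast, among those called with a mean log2 CPM of at least 3 over the libraries compared. A count of 3 in a library, the limit below which no fold was given, was 0.063 to 0.176 CPM. Every contig named by the rule had at least 11 counts in every library compared. PCR copies were not marked by molecular identifiers, so depth limits describe counting error only.

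The size of a response, a measure chosen after the data were seen, was summarised over the 17744 contigs with a mean log2 CPM of at least 3 (prior count 2), as the SD of the log2 change after the variance expected from the spread between replicates had been removed. The correlation of 2 responses was corrected in the same way. Their errors are jackknife SE from leaving out each library in turn. On simulated data set to an SD of 1.2 in petiole, an SD of 0.9 in stem and a correlation of 0.8, over 14939 contigs, these measures returned 1.19, 0.888 and 0.804. The edgeR test was also tested on simulated counts of the 53919 contigs with 200 contigs changed. For submergence in petioles at 1 day it recovered 23% of the contigs changed 2-fold and 65% of those changed 4-fold, and 66.7% and 97.3% of the abundant ones, with 2 wrong calls among 90. For the tissue by treatment interaction at 1 day it recovered 6% and 40%, and 15.2% and 78.4% of the abundant ones, with 5 wrong calls among 51. In this simulation interactions were thus found less often than main contrasts of equal size. The real contrast of petioles at 1 day called 13080 contigs, far more than the 200 changed here. The adjusted threshold is less strict where more contigs change, so the recovered shares do not carry over to the real contrasts.

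Replicates of a group were compared before they were averaged. Their correlation of log2 CPM was 0.885 to 0.951, and the lowest chi-square per degree of freedom between the counts of any pair was 12.9, so no library was treated as a copy of another. The submergence contrasts of the 2 tissues and of the 2 days share no library.

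The alternatives were median-of-ratios size factors in edgeR, library totals alone, no filter and a stricter filter on low counts, DESeq2 1.42.0 (Wald test), limma 3.58.1 (voom), the replicate number as a block, a fit to only the libraries compared, an added bound of 2-fold, and the omission of each library in turn. Added after the data were seen were equal depth (every library thinned to 17617430 estimated counts), the omission of the petiole library farthest from its group in each of the 4 petiole groups, and 3 contrasts: stem against petiole under water on each day, and the tissue by treatment interaction averaged over both days. Calculations used R 4.3.3, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15.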

Results

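Transcript abundance was measured by RNA sequencing in stems and petioles of watercress kept in air or completely under water for 1 day or 2 days, with 3 libraries in each of the 8 groups. The series is about the elongation of stems under water, and the comparisons ask what submergence changed in each tissue and where the tissues differed. Totals ranged from 17617430 to 48928331 estimated counts per library. The mean total of a group was lowest in petioles in air at 1 day and highest in stems under water at 1 day. The 53919 contigs tested are transcript contigs without gene names, so the results are given by contig and by group of contigs. Statements on the strongest changes cover contigs with a mean log2 CPM of at least 3.

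Treatment and tissue separated the libraries. On the first principal component of log2 CPM, with 29.3% of the variance, all 12 libraries from air lay between 75.8 and 132.8 and all 12 libraries from under water between -190.8 and -63.4. On the second component, with 13% of the variance, stems lay between 40 and 95.5 and petioles between -123.2 and 3.9. The petiole library at 3.9, replicate 1 of petioles under water at 1 day, lay nearest to the stems, and the other libraries of its group lay at -46.2 and -72.4. Replicates varied more in petioles, with a median SD of log2 CPM per contig of 0.175 to 0.255 per group, than in stems, with 0.138 to 0.164.

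**Figure D1:**
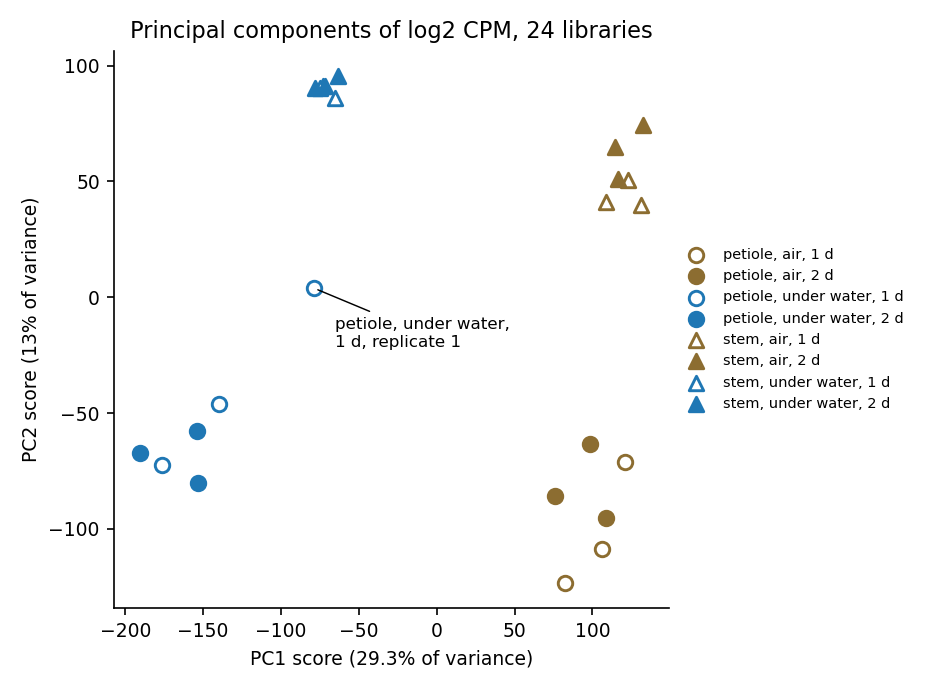
Scores of the 24 libraries on the first component (x axis, 29.3% of variance) and the second component (y axis, 13% of variance) of log2 CPM, with circles for petioles, triangles for stems, brown for air, blue for under water, open symbols for 1 day and filled symbols for 2 days. Libraries from air lie at 75.8 or above on the x axis and libraries from under water at -63.4 or below, and the labelled petiole library lies at 3.9 on the y axis.

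In petioles, 1 day under water raised 7266 contigs and lowered 5814 contigs, together 24.3% of those tested. Among the contigs abundant enough to be named, the strongest rise was that of GEMC01011130.1 (542 bases), from 2.64 ± 0.472 CPM in air to 339 ± 165 CPM under water (SD, n = 3), a log2 change of 7.00 ± 0.57 (SE; edgeR, Benjamini-Hochberg adjusted p = 3.2e-08). GEMC01025816.1 (1549 bases) rose from 1.88 ± 1.08 to 220 ± 122 CPM (log2 change 6.87 ± 0.51, edgeR adjusted p = 9.2e-09). The largest falls were those of GEMC01055134.1 (1515 bases), from 295 ± 49.2 to 1.63 ± 0.338 CPM (log2 change -7.50 ± 0.29, edgeR adjusted p = 4.5e-12), and of GEMC01040125.1 (1490 bases). The latter went from 222 ± 27.2 to 1.28 ± 0.209 CPM (log2 change -7.42 ± 0.25, edgeR adjusted p = 4.5e-13). Of the called contigs, 4532 rose and 3171 fell by at least 2-fold. A fit to the 6 libraries of this comparison alone, which estimates the spread from them, called 6100 contigs, and an added bound of 2-fold left 7703. Without replicate 1 under water 7560 contigs were higher and 7730 lower.

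After 2 days under water the petioles had 8811 contigs raised and 9252 lowered, 33.5% of those tested. GEMC01022795.1 (2327 bases) rose from 1.41 ± 0.265 to 416 ± 20.9 CPM, a log2 change of 8.18 ± 0.31 (SE, n = 3; edgeR, adjusted p = 2.7e-12). GEMC01046308.1 (1515 bases) rose from 2.02 ± 0.477 to 314 ± 64.4 CPM (log2 change 7.26 ± 0.35, edgeR adjusted p = 4.7e-11). The contigs that fell most were GEMC01034916.1 (219 bases), from 287 ± 165 to 1.19 ± 0.114 CPM (log2 change -7.91 ± 1.54, edgeR adjusted p = 0.00056), and GEMC01034917.1 (710 bases). The latter went from 170 ± 106 to 1.09 ± 0.245 CPM (log2 change -7.26 ± 1.55, edgeR adjusted p = 0.0013). These contigs varied between libraries of a group as well. In petioles in air at 1 day GEMC01034916.1 stood at 384, 307 and 6.71 CPM. Under limma-voom the falls at 2 days had adjusted p = 0.064 and 0.11. With an added bound of 2-fold, 10933 contigs were called. With library totals alone 9974 contigs were higher and 7528 lower, so the balance of rises and falls depended on scaling.

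In stems, 1 day under water raised 5384 contigs and lowered 4900, 19.1% of those tested. GEMC01022795.1, which led in petioles at 2 days, rose in stems from 1.34 ± 0.176 to 254 ± 71.5 CPM (SD, n = 3), a log2 change of 7.55 ± 0.30 (SE; edgeR, adjusted p = 3.7e-12). GEMC01071264.1 (674 bases) rose from 1.63 ± 0.492 to 291 ± 51.5 CPM (log2 change 7.47 ± 0.42, edgeR adjusted p = 4.8e-10). In petioles on the same day it stood at 1.25 ± 0.997 CPM in air and 47 ± 17.5 CPM under water, so it was higher under water there too. GEMC01062959.1 (1582 bases) fell from 140 ± 12.4 to 0.549 ± 0.188 CPM (log2 change -8.01 ± 0.33, edgeR adjusted p = 6.3e-12). GEMC01055137.1 (1288 bases) fell from 242 ± 26.4 to 1.1 ± 0.506 CPM (log2 change -7.78 ± 0.28, edgeR adjusted p = 1.5e-12). With an added bound of 2-fold, 5890 contigs were called. With library totals alone the balance turned, to 4304 contigs higher and 5747 lower.

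After 2 days under water the stems had 5584 contigs raised and 5684 lowered, 20.9% of those tested. GEMC01022795.1 again rose most, from 1.5 ± 0.154 to 459 ± 71.2 CPM (log2 change 8.24 ± 0.31, n = 3; edgeR, adjusted p = 1.9e-12). Next was GEMC01046308.1, from 1.90 ± 0.505 to 215 ± 44.7 CPM (log2 change 6.79 ± 0.34, edgeR adjusted p = 1.2e-10). GEMC01059691.1 (1830 bases) fell from 250 ± 38.2 to 1 ± 0.551 CPM (log2 change -7.98 ± 0.40, edgeR adjusted p = 8.6e-11), and GEMC01040125.1 fell from 348 ± 80.9 to 1.47 ± 0.117 CPM (log2 change -7.89 ± 0.25, edgeR adjusted p = 1.7e-13). The balance of rises and falls depended on scaling. With library totals alone 6430 contigs were higher and 4134 lower, 60.9% higher against 49.6% with TMM. Without replicate 1 under water 4467 contigs were higher and 3741 lower. With an added bound of 2-fold, 6028 contigs were called.

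**Figure D2:**
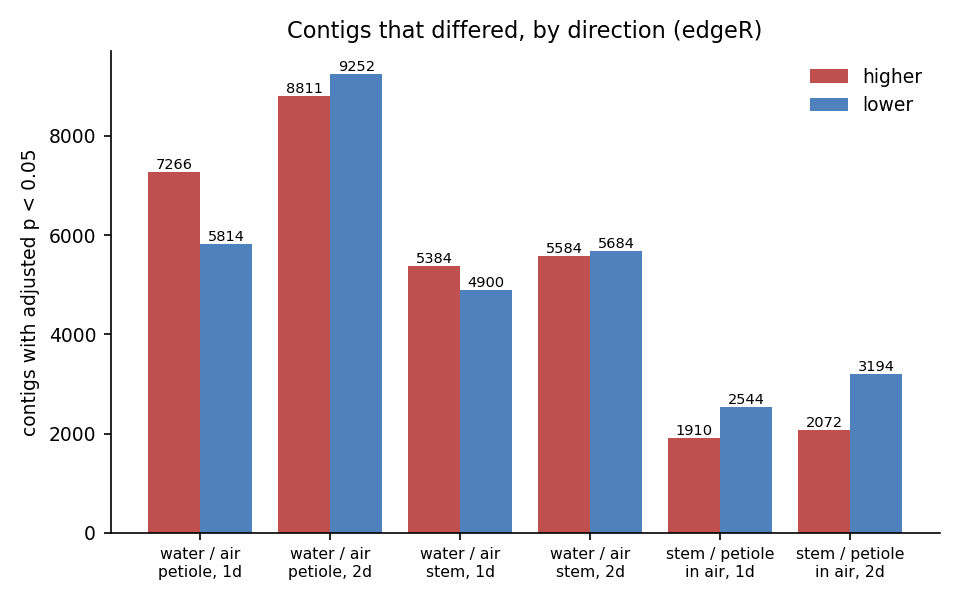
Number of contigs with an adjusted p under 0.05 in edgeR (y axis) that were higher (red) or lower (blue) in the group named first, for submergence against air in each tissue and day and for stem against petiole in air (x axis). Petioles after 2 days under water had 8811 contigs higher and 9252 lower, against 5584 and 5684 in stems. With the spread estimated from the 6 libraries of each comparison, the totals at 2 days were 14057 in petioles and 13125 in stems.

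Most contigs called in either tissue changed with the same sign in the other. Of the 15645 contigs called in petiole or stem at 1 day, 94.7% did so and 7698 were called in the same direction in both. At 2 days 93.8% of 20175 did so, and 9126 were called in the same direction in both. At 1 day, 4261 contigs rose in both petiole and stem and 3437 fell in both, where lists drawn independently would share 726 and 528, and 21 contigs were called in opposite directions. At 2 days 4564 contigs rose in both and 4562 fell in both, against 912 and 975 for independent lists, and 30 were called in opposite directions. GEMC01055134.1, one of the strongest falls in petioles at 1 day, stood in stems at 378 ± 62.6 CPM in air and 2.34 ± 0.688 CPM under water on that day (SD, n = 3). Of the contigs called in petioles, 95.7% changed with the same sign in stems at 1 day and 95% at 2 days. Over the 17744 more abundant contigs, which are not independent replicates, the correlation of the petiole and stem responses corrected for replicate noise was 0.979 ± 0.066 (jackknife SE, 12 libraries) at 1 day and 0.935 ± 0.025 at 2 days.

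The response of petioles was larger than that of stems at 2 days, while at 1 day the ratio lay within 1 jackknife SE of 1 and depended on single libraries. The SD of the log2 changes after removal of replicate noise was 0.868 ± 0.135 in petioles and 0.822 ± 0.03 in stems at 1 day (jackknife SE, 6 libraries each), a ratio of 1.056 ± 0.175. That ratio was between 0.983 and 1.174 with any 1 of the 12 libraries left out, highest without replicate 1 of petioles under water, and 1.262 without the farthest library of each petiole group. A difference between the days is thus not claimed. At 2 days it was 0.945 ± 0.059 in petioles and 0.755 ± 0.016 in stems, a ratio of 1.251 ± 0.083 that stayed between 1.197 and 1.29 with any 1 of the 12 libraries left out. The number of calls does not give the same order in every fit at 1 day. With the spread estimated from the 6 libraries of each comparison, petioles had 6100 calls and stems 11879. The fit to all libraries gave 13080 and 10284. At 2 days the fit to the 6 libraries gave 14057 and 13125, and the fit to all libraries 18063 and 11268. The size of the excess of calls in petioles at 2 days thus depended on the fit.

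**Figure D3:**
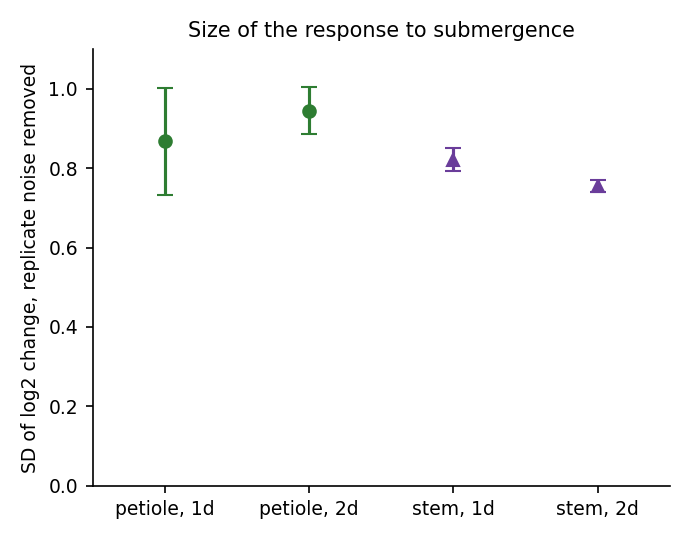
SD over 17744 contigs of the log2 change between under water and air after removal of replicate noise (y axis), for petioles (circles) and stems (triangles) at 1 and 2 days (x axis), with bars of 1 jackknife SE. The petiole value at 2 days, 0.945, lies above the stem value of 0.755, and at 1 day the bars of the tissues overlap.

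Most contigs that changed at 1 day changed the same way at 2 days. In petioles 5311 contigs were raised and 4415 lowered on both days, where independent lists would share 1190 and 998, and in stems 3425 and 3036, against 558 and 517. The noise-corrected correlation of the responses at 1 and 2 days was 0.964 ± 0.07 in petioles and 0.901 ± 0.028 in stems (jackknife SE, 12 libraries, across contigs). The SD of the response at 2 days over that at 1 day was 1.089 ± 0.186 in petioles and 0.919 ± 0.04 in stems.

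The tissue by treatment interaction tested which contigs responded differently in stem and petiole. At 1 day 119 contigs did so, of which 14 were called in both tissues in opposite directions. A further 87 were called in petioles alone, or in both tissues in the same direction but more strongly in petioles. For stems the like number was 18. Contigs called in 1 tissue alone were not sorted by their sign in the other. GEMC01015786.1 (975 bases) had the most negative interaction. It went from 7.47 ± 1.69 to 418 ± 122 CPM in petioles and from 5.27 ± 0.511 to 14.7 ± 2.94 CPM in stems (SD, n = 3). The log2 difference was -4.32 ± 0.38 (SE; edgeR, adjusted p = 1.8e-05). GEMC01030224.1 (1390 bases) went from 4.74 ± 1.89 to 27.8 ± 5.94 CPM in petioles and from 60.1 ± 7.18 to 46.2 ± 8.36 CPM in stems (log2 difference -2.94 ± 0.42, edgeR adjusted p = 0.0026). In the other direction, GEMC01044483.1 (1370 bases) went from 71.5 ± 33.4 to 28.4 ± 14.3 CPM in petioles and from 117 ± 38.8 to 283 ± 75.5 CPM in stems (log2 difference 2.61 ± 0.53, edgeR adjusted p = 0.044). This call ended in 12 of 23 other fits, while the log2 difference stayed between 2.25 and 3.1 with any 1 library left out. The largest positive interaction was that of GEMC01064667.1 (1321 bases, log2 difference 3.48 ± 0.62, edgeR adjusted p = 0.019). It fell in petioles from 137 ± 8.61 to 39.2 ± 7.54 CPM (log2 change -1.80 ± 0.44, edgeR adjusted p = 0.0046). In stems it stood at 25.6 ± 4.98 CPM in air and at 36.3, 182 and 27.5 CPM in the libraries under water. Without the stem library at 182 CPM the log2 difference was 2.12, and the call ended in 7 of 23 other fits.

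The number of contigs with an interaction at 1 day was less firm than the main contrasts. DESeq2 called 670, limma-voom 64, the fit to the 12 libraries compared 15, and the fit without the farthest library of each petiole group 850. With library totals alone 203 were called, 33 with a positive and 170 with a negative interaction, against 38 and 81. Leaving out 1 library gave 53 to 299, and moved the count by over 1.5 times for 10 of the 12 libraries, all but replicates 1 and 3 of petioles in air. The highest number came without replicate 1 of petioles under water.

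At 2 days 326 contigs responded differently in the tissues, of which 27 were called in both tissues in opposite directions. Another 266 were called in petioles alone or more strongly in petioles, and 33 in stems alone or more strongly in stems. GEMC01015786.1 again stood out, at 7.31 ± 1.29 and 531 ± 196 CPM in petioles in air and under water and at 5.08 ± 0.845 and 15.4 ± 3.43 CPM in stems (SD, n = 3; log2 difference -4.59 ± 0.38, edgeR adjusted p = 6.8e-06). For GEMC01030224.1 the log2 difference was -3.73 ± 0.43 (edgeR, adjusted p = 0.00031), with 3.42 ± 0.527 and 32.5 ± 13.5 CPM in petioles and 59.6 ± 16.2 and 43 ± 4.08 CPM in stems. GEMC01064411.1 (3245 bases) fell in petioles from 26.5 ± 7.69 to 1.52 ± 1.08 CPM and stood in stems at 70.6 ± 12.7 CPM in air and 44.9 ± 2.96 CPM under water (log2 difference 3.40 ± 0.44, edgeR adjusted p = 0.001). GEMC01039162.1 (1053 bases) was at 38.9 ± 6.06 and 3.39 ± 0.16 CPM in petioles and at 39.2 ± 0.584 and 17.5 ± 2.51 CPM in stems (log2 difference 2.35 ± 0.27, edgeR adjusted p = 0.00031). All 4 of these calls held in each of 23 other fits. DESeq2 called 1236 contigs, limma-voom 201, and the fit without the farthest library of each petiole group 601. Leaving out 1 library gave 124 to 331, with a change of over 1.5 times for 10 of the 12 libraries, all but replicate 3 of petioles in air and under water.

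The interactions of the 2 days came from different libraries and went together. Of the 119 contigs called at 1 day 118 had an interaction of the same sign at 2 days, and of the 326 called at 2 days 312 had the same sign at 1 day. Both days called 68 contigs with the same sign, GEMC01015786.1 and GEMC01030224.1 among them, where independent lists would share 0.37.

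**Figure D4:**
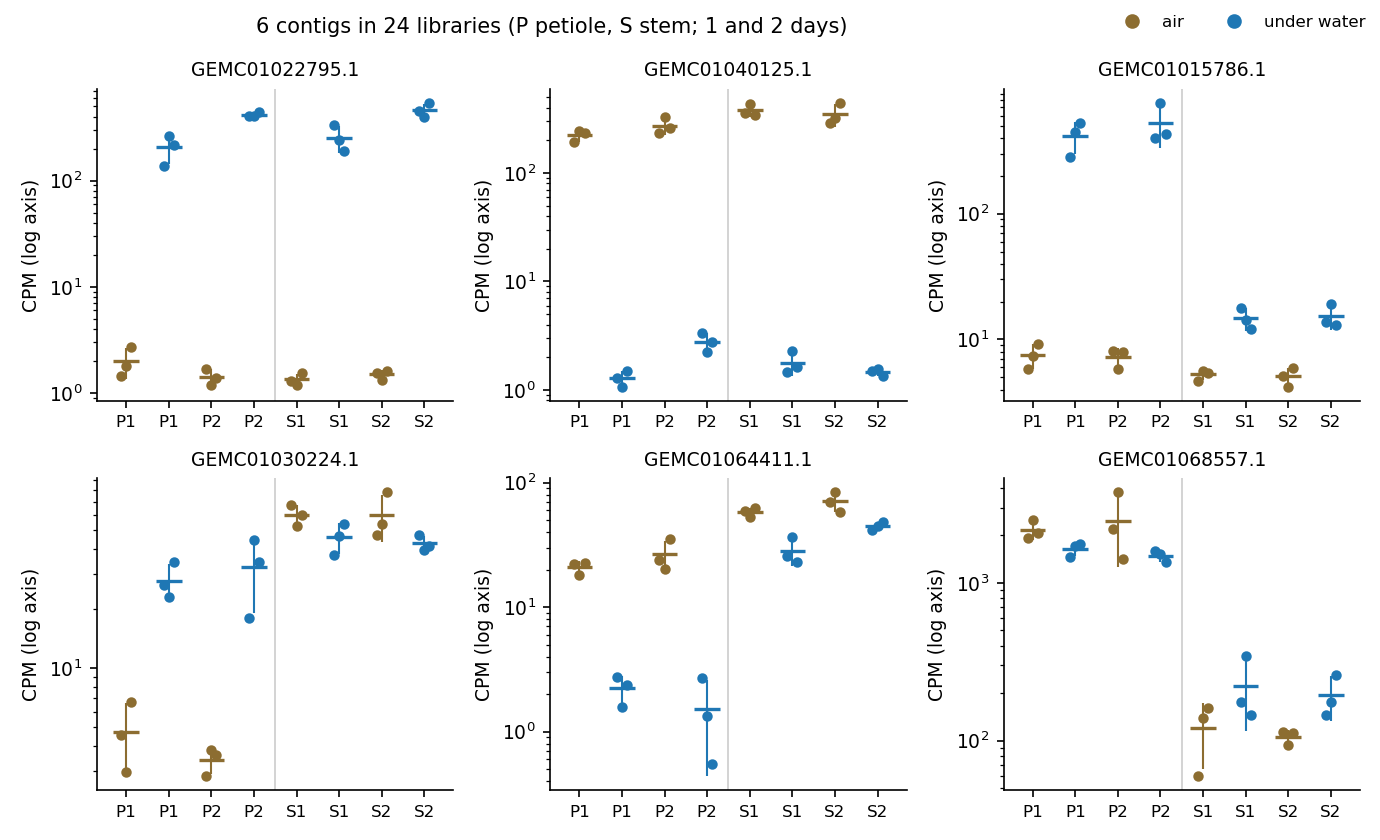
CPM on a log axis (y axis) of 6 named contigs in each library (points) of the 8 groups (x axis; P petiole, S stem, 1 and 2 days; brown air, blue under water), with the mean (horizontal line) and SD (vertical line) of each group. GEMC01022795.1 rose and GEMC01040125.1 fell in both tissues, GEMC01015786.1 reached 418 CPM in petioles and 14.7 CPM in stems after 1 day under water, and GEMC01068557.1 was far higher in petioles than in stems.

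The time by treatment interaction tested which responses differed between 1 and 2 days. In petioles it was found for 107 contigs, of which 60 had a more positive and 47 a more negative change at 2 days. GEMC01042733.1 (1676 bases) stood at 13.5 ± 4.64 CPM in air and 6.45 ± 1.64 CPM under water at 1 day, and at 9.46 ± 3.61 and 30.3 ± 8.72 CPM at 2 days (SD, n = 3; log2 difference 2.76 ± 0.46, edgeR adjusted p = 0.027). GEMC01029624.1 (416 bases) moved from 16.3 ± 6.74 and 6.41 ± 0.937 CPM to 14.2 ± 2.87 and 35.4 ± 13.6 CPM (log2 difference 2.68 ± 0.46, edgeR adjusted p = 0.029). The interaction of GEMC01022711.1 (891 bases; log2 difference -3.26 ± 0.53, edgeR adjusted p = 0.024) came with a change of the controls. They went from 2.81 ± 0.412 CPM in air at 1 day to 16.8 ± 5.02 CPM at 2 days, beside 13 ± 3.51 and 8.07 ± 0.666 CPM under water. GEMC01064105.1 (1448 bases) was at 76.2 ± 14.6 and 25.7 ± 3.73 CPM at 1 day and at 87.7 ± 19.4 and 8.38 ± 2.76 CPM at 2 days (log2 difference -1.81 ± 0.36, edgeR adjusted p = 0.045). This call ended in 16 of 22 other fits, that of GEMC01029624.1 in 7, and those of GEMC01042733.1 and GEMC01022711.1 in 5 each. The count was 1049 with DESeq2, 17 with limma-voom, 5 in the fit to the 12 libraries compared and 71 with the replicate number as a block. It was 58 without a filter on low counts and 174 with the stricter filter. Library totals alone gave 65 positive and 28 negative interactions, 69.9% positive against 56.1%, and the omission of 1 library gave 7 to 159. The libraries that moved it by over 1.5 times were replicate 2 of petioles in air (7) and under water (10) at 1 day, replicates 1, 2 and 3 in air at 2 days (19, 51 and 69), and replicates 1 and 2 under water at 2 days (34 and 26).

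In stems the time by treatment interaction was found for 71 contigs, 47 more positive and 24 more negative at 2 days. GEMC01011130.1, the strongest rise in petioles at 1 day, stood in stems at 281 ± 101 CPM under water at 1 day and 40.2 ± 7.53 CPM at 2 days (SD, n = 3). In air it stood at 1.89 ± 0.369 and 3.99 ± 1.33 CPM (log2 difference -3.87 ± 0.66, edgeR adjusted p = 0.023). GEMC01024297.1 (1848 bases) went from 548 ± 103 to 85.1 ± 14.2 CPM under water and stood at 4.41 ± 0.328 and 4.28 ± 0.229 CPM in air (log2 difference -2.65 ± 0.43, edgeR adjusted p = 0.019). GEMC01017346.1 (921 bases) was at 18 ± 1.54 and 5.30 ± 1.02 CPM in air and under water at 1 day and at 15.5 ± 0.364 and 16.2 ± 5.54 CPM at 2 days (log2 difference 1.83 ± 0.30, edgeR adjusted p = 0.019). GEMC01016520.1 (771 bases) had a log2 difference of 1.74 ± 0.34 (edgeR, adjusted p = 0.045). Of the 71 contigs, 22 had risen and 30 had fallen more strongly at 1 day. The count was 917 with DESeq2, 365 in the fit to the 12 libraries compared, 160 with the stricter filter and 256 without the farthest library of each petiole group. Library totals alone gave 250 positive and 32 negative interactions. The omission of 1 library gave 4 to 101, with 4 to 25 for 9 of the 12 libraries, all but replicate 3 in air and replicate 1 under water at 1 day and replicate 3 under water at 2 days. Each of these 4 contigs lost its call in 6 to 12 of 22 other fits. Of the petiole contigs with a time by treatment interaction 101 of 107 had the same sign in stems. Further, 17 were called in both tissues with the same sign, where independent lists would share 0.073.

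Stem and petiole in air differed in 4454 contigs at 1 day (1910 higher in stem, 2544 lower) and in 5266 at 2 days (2072 higher, 3194 lower). GEMC01068557.1 (1431 bases) was among the most petiole-rich, at 2460 ± 1190 CPM in petioles and 106 ± 10.1 CPM in stems at 2 days (SD, n = 3; log2 difference -4.54 ± 0.41, edgeR adjusted p = 9.6e-07). GEMC01001247.1 (1978 bases) was lower in stems on both days, with log2 differences of -4.48 ± 0.43 at 1 day and -4.63 ± 0.43 at 2 days (edgeR, adjusted p = 2.4e-06 and 1.2e-06). So was GEMC01064664.1 (1037 bases) at 1 day, with 46.4 ± 33.4 CPM in petioles and 2.23 ± 1.06 CPM in stems (log2 difference -4.39 ± 0.85, edgeR adjusted p = 0.0021). Among stem-rich contigs, GEMC01049858.1 (1995 bases) stood at 103 ± 10.2 CPM in stems and 5.73 ± 4.47 CPM in petioles at 1 day (log2 difference 4.19 ± 0.77, edgeR adjusted p = 0.0013). GEMC01030888.1 (1456 bases) stood at 49 ± 16.3 and 2.69 ± 0.845 CPM (log2 difference 4.18 ± 0.43, edgeR adjusted p = 6.3e-06). At 2 days GEMC01030224.1, one of the contigs with a tissue by treatment interaction, was higher in stems by a log2 difference of 4.13 ± 0.33 (edgeR, adjusted p = 3.3e-07) and GEMC01033616.1 (712 bases) by 3.97 ± 0.55 (edgeR, adjusted p = 6.6e-05). Both days called 1111 contigs higher and 2171 lower in stem, where independent lists would share 73.4 and 151. The excess of contigs lower in stem depended on scaling. Library totals alone gave 4923 higher and 1753 lower at 1 day, and 4502 higher and 2397 lower at 2 days. A fit to the 6 libraries compared called 2066 at 1 day, and without replicate 1 of stems in air 3457 were called at 2 days. The contigs higher in stem fell to 1092 at 1 day without replicate 1 and 1199 without replicate 3 of stems. At 2 days they fell to 1136 and 1102 without replicates 1 and 2 of stems, and to 1291 and 1288 without replicates 2 and 3 of petioles.

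Few contigs were called between 1 and 2 days in air. In petioles there were 8, of which 7 were higher at 2 days. Among these were GEMC01064812.1 (2530 bases), from 10.2 ± 1.42 to 31.4 ± 7.7 CPM (SD, n = 3; log2 change 1.61 ± 0.26, edgeR adjusted p = 0.048), and GEMC01068444.1 (4037 bases). The latter went from 17.1 ± 1.72 to 29 ± 2.83 CPM (log2 change 0.76 ± 0.13, edgeR adjusted p = 0.048). GEMC01022711.1, named above for its time by treatment interaction in petioles, was also among the 7 (log2 change 2.57 ± 0.39, edgeR adjusted p = 0.031). The contig that was lower, GEMC01068786.1, falls outside the rule for named contigs and was chosen after its values were seen. Its means were 6.16 CPM at 1 day and 0.0113 CPM at 2 days. DESeq2 called 277 contigs in petioles and limma-voom 0, and 3875 contigs had an unadjusted p under 0.05. With median-of-ratios scaling 3 were higher and 1 lower. The omission of 1 library gave 33 without replicate 3 at 1 day, 5 without replicate 2 at 1 day, and 3 without replicate 1 or replicate 3 at 2 days. GEMC01064812.1 lost its call in 11 and GEMC01068444.1 in 12 of 16 other fits. In stems edgeR called 0 contigs, with 1288 at an unadjusted p under 0.05, DESeq2 called 40 and limma-voom 0. With edgeR the count was 1 without replicate 2 at 1 day and 3 without replicate 3 at 1 day.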

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

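The tests of depth and of leaving out 1 library for the size of the petiole response, and the comparisons of interaction signs between days and tissues, were chosen after the result was seen. The results here are differences between tissues or between days in the response to submergence, tested as interactions in edgeR, and a ratio of response SDs between the tissues, given with its jackknife SE.

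GEMC01015786.1 rose far more in petioles than in stems on both days, with interactions of -4.32 ± 0.38 at 1 day and -4.59 ± 0.38 at 2 days (log2, SE). GEMC01030224.1, stem-rich in air, had interactions of -2.94 ± 0.42 and -3.73 ± 0.43. At 2 days GEMC01064411.1 (3.40 ± 0.44) and GEMC01039162.1 (2.35 ± 0.27) fell more in petioles than in stems. At 1 day the calls of the positive interactions of GEMC01064667.1 (3.48 ± 0.62) and GEMC01044483.1 (2.61 ± 0.53) depended on the libraries and tools used. The log2 difference of GEMC01044483.1 stayed between 2.25 and 3.1 with any 1 library left out. Between days, GEMC01042733.1 (2.76 ± 0.46) and GEMC01029624.1 (2.68 ± 0.46) had a more positive and GEMC01022711.1 (-3.26 ± 0.53) and GEMC01064105.1 (-1.81 ± 0.36) a more negative change at 2 days in petioles. In stems the same held for GEMC01017346.1 (1.83 ± 0.30) and GEMC01016520.1 (1.74 ± 0.34), and for GEMC01011130.1 (-3.87 ± 0.66) and GEMC01024297.1 (-2.65 ± 0.43). Each of these calls between days ended in 5 to 16 of 22 other fits. For GEMC01022711.1 the petiole controls in air changed as well, from 2.81 ± 0.412 CPM at 1 day to 16.8 ± 5.02 CPM at 2 days.

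The tissues differed in their response in 119 contigs at 1 day and in 326 at 2 days, and the days in 107 contigs in petioles and 71 in stems. For each of these counts 25 of the 200 possible splits were drawn, in which libraries of the same treatment were reassigned between tissues or days. For the tissue by treatment interaction at 1 day 3 of the 25 splits gave as many contigs, the real one included, with a highest other count of 3302. At 2 days 3 of the 25 did, with a highest other count of 1338. By these counts alone chance is not excluded. The larger counts came from splits that exchanged the tissue of most or all libraries of 1 treatment and so brought the difference between stem and petiole into the interaction, a structure of the samples. Such splits are no comparison without a difference, so the counts say little about chance here. The separate libraries of the 2 days go against chance as the whole source: 118 of the 119 contigs had the same sign at 2 days, and 68 were called on both days with the same sign, against 0.37 for independent lists. For the time by treatment interaction in petioles 3 of the 25 splits gave as many, with 1012 as the highest other count, so that chance is not excluded by the count alone. That split exchanged replicate 1 of petioles in air at 1 day with replicate 3 at 2 days, which points to a structure among the petiole libraries in air other than the day. In the separate libraries of stems 101 of the 107 contigs had the same sign. Further, 17 were called in both tissues with the same sign, against 0.073 for independent lists. This goes against chance as the whole source only if the samples of the 2 tissues are independent. Whether they share plants is not stated. Deviations of stem and petiole libraries of the same treatment, time and number had a mean correlation of 0.026. In stems only the real split of the 25 (1 split) gave 71 or more, and the highest other count was 53. That share is the smallest that 25 draws can give. The split with 53 exchanged only replicate 1 of stems in air at 1 day with replicate 3 at 2 days. Chance is thus not excluded by the count alone in stems either. The count was 4 to 25 without 1 of 9 libraries, all but replicate 3 in air and replicate 1 under water at 1 day and replicate 3 under water at 2 days.

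The response of petioles to 2 days under water was larger than that of stems, with a ratio of response SDs of 1.251 ± 0.083 (jackknife SE). With every library thinned to the same total the ratio was 1.25. The measure removes noise between replicates, counting noise included, so thinning could hardly move it. The thinning thus does not decide on library depth. A petiole library standing apart is argued against, since the lowest ratio with 1 library left out was 1.197. A difference between the tissues in their response to submergence may remain as a hypothesis, and was not tested apart from these explanations.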

How the results depend on the processing

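Equal depth, the fits without the petiole library farthest from its group and the check of replicate numbers within each tissue were chosen after the data were seen. No contig named by the rule changed its sign under any alternative run. The balance of higher and lower contigs was less stable. With library totals alone it turned for submergence in petioles at 2 days, for submergence in stems on both days and for stem against petiole in air on both days, and with only the libraries compared the order of the petiole and stem counts at 1 day turned. The near-even balances of both tissues at 2 days turned in other fits too. For the contigs named by the rule, each call was checked once per alternative, so the checks number more than the fits. The call was kept in 395 checks with other settings and in 268 checks without 1 library. It was lost in 33 and 80 such checks. Counts of the submergence contrasts stayed within 1.5 times under each setting except 2. A fit to only the libraries compared gave 6100 in petioles and 11879 in stems at 1 day, and 14057 and 13125 at 2 days. It gave 2066 for stem against petiole in air and 15 for the tissue by treatment interaction at 1 day. For the time by treatment interaction it gave 5 in petioles and 365 in stems, and for the days in air 0 in petioles. This fit takes the spread from the compared libraries alone. The submergence and time by treatment counts fell in petioles but rose in stems, so fewer libraries alone do not account for the changes. The fit to all libraries shares an estimate of the spread across both tissues. Replicates varied more in petioles (median SD of log2 CPM 0.175 to 0.255 per group) than in stems (0.138 to 0.164). The falls in petioles and the rises in stems go with this order. A bound of 2-fold, which removes smaller changes by construction, left 7703 and 10933 in petioles at 1 and 2 days, 5890 and 6028 in stems, and 2401 and 2848 for the tissues in air. Apart from that bound, the cause of the changes was not tested. DESeq2 called 670 and 1236 contigs for the tissue by treatment interaction at 1 and 2 days, 1049 and 917 for the time by treatment interaction in petioles and stems, and 277 and 40 for the days in air. limma-voom called 64 and 201 for the tissue by treatment interaction, 17 for the time by treatment interaction in petioles and 0 for the days in air in petioles. Library totals alone gave 203 for the tissue by treatment interaction at 1 day and 282 for the time by treatment interaction in stems, and moved the median log2 change of all contigs by -0.112 for submergence in stems at 1 day, -0.167 for the tissue by treatment interaction at 1 day, 0.191 for the time by treatment interaction in stems, and 0.217 and 0.173 for the tissues in air. Median-of-ratios scaling gave 4 for the days in air in petioles, and so did no filter (4), which gave 58 for the time by treatment interaction in petioles. The stricter filter gave 174 and 160 for that interaction in petioles and stems. Without the farthest petiole libraries (replicate 1 of petioles under water at 1 day and replicate 3 of the other petiole groups), 850 and 601 contigs had a tissue by treatment interaction, 256 a time by treatment interaction in stems, 14 and 1 differed between days in air, and the ratio of response SDs at 1 day was 1.262. With 1 library left out, the counts ranged from 53 to 299 and from 124 to 331 for the tissue by treatment interaction at 1 and 2 days, from 7 to 159 and from 4 to 101 for the time by treatment interaction in petioles and stems, from 3457 to 4390 for the tissues in air at 2 days, and from 3 to 33 and from 0 to 3 for the days in air.

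The labels number the replicates alike in all groups, but do not say what a number shares, and the bar for paired libraries was not met: the correlation of deviations from the group means averaged 0.011 for the same number (-0.111 to 0.175), was over 0.1 in 6 of 84 pairs, and 11 of 24 libraries matched best with their own number. In petioles alone the numbers did carry a weak shared structure. Their 18 pairs averaged 0.061, and of the 216 ways to assign the numbers within groups only the real one (1) gave so high a mean, against 61 of 216 in stems, with a mean of 0.008. With the replicate number as a block, 71 contigs had a time by treatment interaction in petioles, and 121 and 324 a tissue by treatment interaction. No count other than the 71 moved by over 1.5 times. This block was common to both tissues, so a structure of the petioles alone was not fitted. With stem and petiole of the same number as a block in limma-voom, 75 contigs had a tissue by treatment interaction at 1 day. Another counting unit and the alternatives of the gene list tests were not run, since no identifier names a gene. Depth limits the contigs of low count: the floor of 3 counts was 0.063 to 0.176 CPM.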

Other observations

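Tests chosen after the result was seen were the splits of 6 libraries, the test of chance between libraries for stem-rich contigs, the allowances for spread in the tests of stem tissue and of a weaker response, and the contrasts of stem and petiole under water and of the mean of both days.

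Some contigs were found in 1 treatment only within a tissue. In petioles 19 contigs had at least 10 counts in each of the 6 libraries from under water and 0 counts in each of the 6 from air, and 10 had the reverse. The median count of the 19 contigs in a library from under water was 41, and 14 of them had counts in stems in air. In stems 7 contigs had such counts only under water, with a median of 70, and 9 only in air; some of the 7 had counts in petioles in air.

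Under water the tissues differed in 5880 contigs at 1 day (2459 higher in stem, 3421 lower) and in 10101 at 2 days (5016 higher, 5085 lower), beside 4454 and 5266 in air. The count at 1 day depended on single libraries. It was 3493 and 3655 without replicates 2 and 3 of petioles, and 3894 and 3760 without replicates 1 and 3 of stems. Without replicate 1 of petioles it was 8530 and the split turned, to 4476 higher and 4054 lower. At 2 days it was 6562 without replicate 2 of petioles and 6584 without replicate 3 of stems. With library totals alone the split under water at 2 days was 7008 higher and 3521 lower. Averaged over both days the tissue by treatment interaction was called for 1292 contigs, 551 with a more positive change in stem and 741 with a more negative one, or 54.1% positive with median-of-ratios scaling and 23.8% with library totals, against 42.6%. Without replicate 1 of petioles under water at 1 day 2315 were called (1167 positive, 1148 negative). Leaving out any other library gave at least 867. The negative ones fell to between 475 and 493 without replicates 1 or 3 of stems in air or replicate 2 of petioles under water at 1 day, or replicate 1 of petioles or replicate 3 of stems under water at 2 days. Among the 326 contigs with such an interaction at 2 days, 84 were higher in petioles under water and not called in stems, with a median log2 change of 2.25 in petioles and 0.11 in stems, and 91 were lower in petioles and not called in stems, with -1.22 and -0.07. A further 60 rose in both tissues but more in petioles (3.21 and 1.46), and 31 fell in both but more in petioles (-3.19 and -1.42).

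Contigs that follow each other in the numbering of the identifiers responded alike, with a correlation of their log2 changes across 41799 pairs of 0.247 in petioles at 1 day and 0.223 in stems at 2 days, against 0.001 and 0.002 for random pairs; contigs are not independent replicates. With runs of neighbours called in the same direction counted once, the submergence counts were 9919 and 13015 in petioles and 7895 and 8778 in stems. Called contigs were longer than the rest: in petioles at 1 day the median length was 1239 bases for those that rose, 1103.5 for those that fell and 982 for those not called.

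Splits of the 6 libraries of a comparison number 10, too few for a share under 0.05. The real split, 1 of the 10, called 13080 contigs in petioles at 1 day against 2392 for the highest other split, 18063 against 2 in petioles at 2 days, 10284 against 1 in stems at 1 day and 11268 against 1 in stems at 2 days. For stem against petiole in air the numbers were 4454 against 9 at 1 day and 5266 against 1 at 2 days, each with 1 split of 10. For 2 days against 1 day in air they were 8 against 6 in petioles (1 split of 10) and 0 against 1 in stems, where all 10 splits gave at least as many.

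Replicate 1 of petioles under water at 1 day lay nearest to the stems on the second component and deviated most from its group, with a median absolute deviation of 0.317 (log2). Replicate 1 also lay nearest to the stems in every other petiole group, at -71 and -63.2 in air at 1 and 2 days and at -57.7 under water at 2 days. In every petiole group replicate 2 lay next and replicate 3 farthest from the stems, so the position goes with the replicate number. Stem tissue in that sample stays open. Its 188 stem-rich contigs exceeded the other replicates by 0.033 of the difference between the tissues, while 141 petiole-rich contigs fell short by 0.407, and admixture would move both by a like share. But in replicate 3 these shares were -0.029 and -0.24, which differ by 0.211 and so by more than the 0.15 set as the bound, and the test cannot decide. A weaker response of the whole sample stays open too. The slope of replicate 1 on the stem response over 4680 contigs was 0.803 of the mean slope of the other replicates. These contigs were called in both tissues at 2 days, with log2 changes less than 0.3 apart. The slopes of the other replicates, 0.951 and 1.036, had a relative SD of 0.061. The ratio is thus too near the bound of 0.8 set for this test to decide. The labels do not say what replicates of the same number share, and no biological explanation was tested.

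Contigs at least 2-fold richer in stems than in petioles in air at 1 day (985 contigs) had a median log2 change at 2 days under water of 0.26 ± 0.284 in petioles (jackknife SE) and -0.09 ± 0.206 in stems, with 302 called higher and 179 lower in petioles. Of the 55 of these contigs with a tissue by treatment interaction, 50 had a negative one. The 1416 petiole-rich contigs chosen in the same way had medians of -0.13 ± 0.143 in petioles and 0.13 ± 0.104 in stems, and 29 of their 32 interactions were positive. Stem tissue in the submerged petiole samples was predicted to raise at least 75% of 43 strongly stem-specific contigs by more than 0.02 of the stem level. Of these contigs 41.9% ± 7.5 (counting SE) rose in petioles by more than this and 21 fell. The median rise was 0.0093 of the stem level. The changes of single contigs ranged from -0.634 to 0.675 of the stem level. Their own changes in petioles can thus hide a shift of 0.02, and the test cannot decide on stem tissue. Stem tissue in these samples stays open, and 41.9% also lies within 2 counting SE of the bound of 50% set against it. The counting SE treats the contigs as independent, which they are not. Chance between libraries may account for the median shift, which was 0.92 of its jackknife SE.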
